A study of Ovis aries with 16 samples.

How the data were processed

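Small non-coding RNA was sequenced from liver (tip of the left lobe) and from vastus lateralis, a thigh muscle, of 8 female Suffolk sheep. Per the labels' protocols, the mothers of 4 animals were injected daily under the skin with bisphenol A (BPA), a plastics monomer with oestrogen-like activity, at 0.5 mg per kg from day 30 to day 90 of gestation. The mothers of the other 4 received corn oil alone. The offspring were sampled at about 21 months of age, after a fast of 48 hours and 24 hours after the second of 2 prostaglandin injections given 11 days apart. Total RNA was extracted with Trizol and an RNeasy column and made into libraries with a NEBNext small RNA kit, per the labels' protocols. Each of the 16 libraries is 1 tissue of 1 animal, and the replicate number is the animal's number, so a liver and a muscle library with the same number come from the same sheep.

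The submitters' processing notes name cutadapt 3.2, STAR 2.6.0c and featureCounts 1.6.1 without giving their roles. The genome build, the annotation and the normalization tool are not given in the sources used here. The authors deposited 4 tables of normalized counts, a signal in which each value is a read count divided by 1 size factor per library. They cover 105 miRNAs, 694 snoRNAs, 1148 snRNAs and 2973 lncRNAs. In each library every deposited value was a whole multiple of a single step, within a tolerance of 0.001, so whole reads were recovered for 100% of the values. Within each tissue the median ratio to the mean profile was the same in all 8 libraries of a table. The size factors were therefore set separately in each table and in each tissue, and values from different tables or tissues share no common scale. Against a scale set over both tissues together, the deposited muscle-minus-liver difference was offset by -0.59 log2 units for miRNAs, -0.70 for snoRNAs, -1.48 for snRNAs and 0.40 for lncRNAs. The tests had been fixed without knowledge of this, so log2 tissue differences are given on the deposited scale and after median-of-ratios rescaling over both tissues.

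Recovered reads per library, summed over the 4 tables, ranged from 159650 to 2146593. The miRNA reads ranged from 94393 to 1383538 and the snRNA reads from 877 to 58486. These are reads assigned to the listed transcripts, not the sequenced total, which is unknown. No pair of libraries within a group agreed within sampling noise (smallest chi-square per degree of freedom 9.1), so all 16 were treated as separate samples.

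The main test, fixed before the data were examined, was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(deposited value + 1). Transcripts with a mean deposited value of at least 5 over the libraries of the fit were tested, two-sided, with Benjamini-Hochberg adjustment within each table and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low transcripts. BPA was compared with control within each tissue, 4 libraries against 4. The tissue difference (muscle minus liver) and the BPA by tissue interaction used all 16 libraries in 4 groups. The numbers pair the libraries because each marks 1 animal, but the deviations of a liver and a muscle library of the same animal from their group means correlated by only -0.24 to 0.13 across 360 transcripts, and in 1 of the 8 animals was the own muscle library the closest. The fit with the animal as a block was an alternative.

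Gene lists were also fixed before the data were examined. Names in the miRNA table matched lists of fibroblast and smooth-muscle, fibrosis-related, insulin and lipid metabolism, let-7, miR-17/92 and DLK1-DIO3 region miRNAs. These were tested with camera at a preset correlation of 0.01 where at least 3 members were tested. The liver-enriched, leukocyte and endothelial lists had fewer than 3 members and are given by member. All lists of snoRNAs, snRNAs and lncRNAs matched no name, because the files identify nearly all transcripts of these classes by number only. The lists of muscle-enriched and erythroid miRNAs also matched no name, although all 105 miRNAs are named. MIR133 carries no letter, while the muscle-enriched list holds miR-133a and miR-133b, so it did not match. Named transcripts are, per comparison and table, the 3 higher and the 3 lower with the smallest p that have a name and a mean value of at least 10. Of transcripts with an identifier only, at most 2 that rose and 2 that fell are given per comparison. Called list members are named up to 4 per list. Names, lengths and nesting of transcripts come from the RefSeq gene table of the sheep assembly ARS-UI_Ramb_v3.0, which may differ from the build the authors used, so no coordinates are given. Of transcripts with reads, it held 100% of the miRNAs, 92.1% of the snoRNAs, 82.9% of the snRNAs and 48.2% of the lncRNAs.

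The agreement of the BPA effects between tissues was measured as Pearson's r across transcripts, with an exact permutation of treatment over the 8 animals (70 assignments). Read totals per class were compared by exact permutation, for which 4 libraries against 4 can give no p below 0.0286. The analysis was tested on simulated reads with 200 changed transcripts. In the liver comparison, limma called 40.6% of transcripts changed 2-fold, 61.1% of those changed 4-fold and 91.5% of those changed 8-fold. In the muscle comparison it called 59.7%, 96.7% and 100%. The simulated groups shared 1 mean profile and 1 dispersion per table, with changes in random directions and known size factors. The rates therefore cover neither a shift in the shares of the classes nor errors in the size factors. A simulated shift of 1 log2 unit in a list was called in 100% of 100 runs for the liver miRNA table, and with no shift some list was called in 8%. These runs drew each miRNA independently. In the liver data the shifted list, that of insulin and lipid metabolism, had an estimated correlation of 0.4959. Both rates are thus unknown for lists with correlated members. Alternatives covered the pseudocount (0.5 and 5), the filter (none and 20), rescaling by median of ratios or quantiles, robust variance estimation, the adjustment, a fold-change minimum of 0.5, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, 1 fit over all 16 libraries, the range of library codes in the labels as a covariate (meaning not given in the sources used here), and leaving out each replicate. Other scalings, thinning of reads, and the removal of duplicated or nested loci were chosen after seeing the data.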

Results

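Small RNA libraries from liver and thigh muscle of 21-month-old female sheep were compared between 4 animals exposed to BPA before birth and 4 control animals. The question was how prenatal BPA affects non-coding RNA in these tissues of the adult offspring. Reads assigned to miRNAs numbered 94393 to 240815 in the 4 control livers and 578150 to 1383538 in the 4 BPA livers. They numbered 471691 to 559705 in control muscle and 596919 to 1044886 in BPA muscle. All values below are deposited normalized counts, given as mean ± SD with n = 4 per group unless stated. The animals are separate biological replicates.

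The classes of RNA differed in share between groups before any transcript was tested. snRNAs, the RNAs of the splicing machinery, gave 29.2 ± 12.9 reads per 100 miRNA reads in control livers and 0.192 ± 0.062 in BPA livers (exact permutation p = 0.0286, the smallest possible with 4 against 4, and 0.0445 after Benjamini-Hochberg adjustment over 14 tests). Muscle of the same animals gave 0.271 ± 0.0436 in controls and 0.382 ± 0.256 in BPA animals (exact p = 0.6286, adjusted 0.6770). snoRNAs, which guide the modification of ribosomal and spliceosomal RNA, gave 5.84 ± 2.2 reads per 100 miRNA reads in control livers and 1.94 ± 1.02 in BPA livers (exact p = 0.0286, adjusted 0.0445). In muscle the order was the opposite, with 0.629 ± 0.0471 in controls and 1.78 ± 0.605 in BPA animals (exact p = 0.0286, adjusted 0.0445). lncRNA reads per 100 miRNA reads differed by less than the spread in liver (19.8 ± 2.06 and 18.3 ± 2.31, exact p = 0.3429, adjusted 0.4000).

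**Figure D1:**
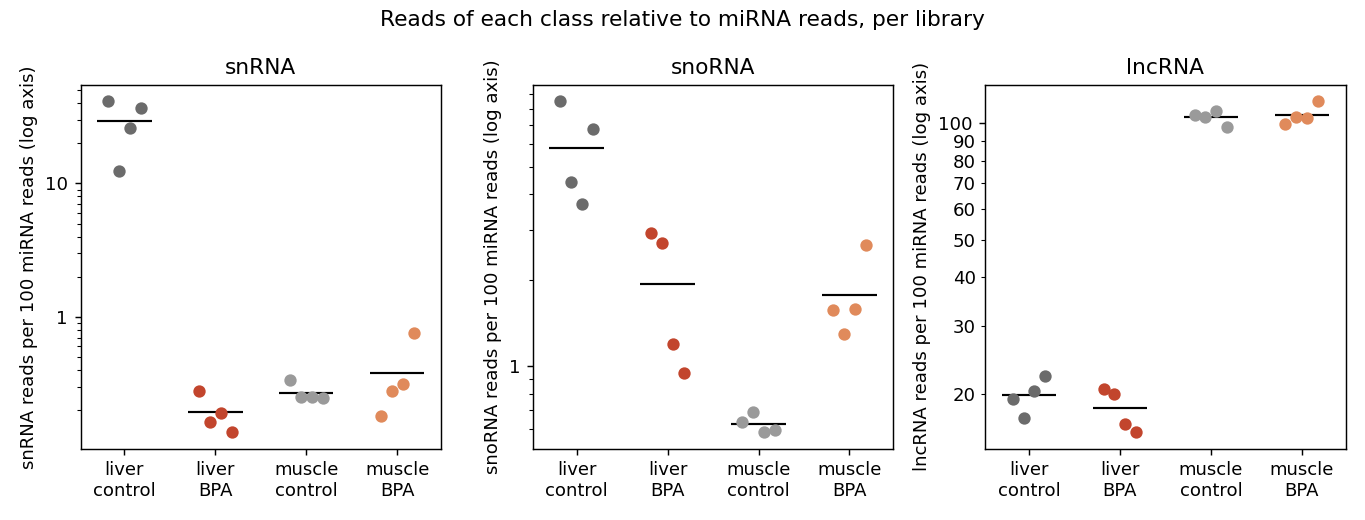
Reads of snRNAs, snoRNAs and lncRNAs per 100 miRNA reads (log axes) in each of the 16 libraries, with a line at the group mean (n = 4). The 4 control livers lie between 12.4 and 41.2 snRNA reads per 100 miRNA reads, and the other 12 libraries between 0.137 and 0.756.

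In livers of BPA animals, 5 miRNAs rose and 4 fell among 78 tested. MIR200B, a miRNA of epithelial cells, had the smallest p, with values from 174 to 453 in control livers and from 980 to 1395 in BPA livers (log2 fold change 2.07 ± 0.30 SE, limma, BH-adjusted p = 7.08e-04). MIR30B fell from 1308 ± 220 to 392 ± 199 (log2 fold change -1.87 ± 0.35, limma adjusted p = 0.0048), and the more abundant MIR26B fell from 20037 ± 4894 to 9734 ± 1633 (-1.03 ± 0.20, adjusted p = 0.0055). MIR125B rose from 3734 ± 1113 to 8547 ± 3315, and MIR25 from 1649 ± 365 to 3018 ± 717 (limma adjusted p = 0.0361 and 0.0417). MIR22, which the naming rule did not cover and which was chosen after its values were seen, also rose (log2 fold change 0.85, limma adjusted p = 0.0496). For each of these 6 miRNAs all 4 BPA livers lay on the same side of all control livers. BPA livers 910 and 918 (codes 95 and 96) lay farther from the controls than 977 and 984 (codes 71 and 72) for MIR30B, MIR125B, MIR22 and MIR25. For MIR26B the order was the opposite, and for MIR200B these livers overlapped. In BPA liver 984, MIR125B was at 4716 (controls up to 4485) and MIR22 at 4192 (controls up to 3974). The calls of MIR125B and MIR25 lay near the threshold and were lost on leaving out any of several single libraries. Their log2 fold changes in those fits were 0.91 to 1.23 and 0.70 to 0.96, against 1.16 and 0.87 with all libraries. The call of MIR22 was lost without BPA 910 and without BPA 918, where other miRNAs made up all the calls. Its values in the fits without single libraries were not recorded. Without control 902, BPA 910, BPA 918 or BPA 977, MIR125B had a limma adjusted p of 0.0658, 0.1361, 0.1058 and 0.0578 (7.65e-06 to 0.1361 over all alternatives), and MIR25 did not pass without any single liver replicate except BPA 984 (0.0502 to 0.1361; 5.55e-05 to 0.1361 over all alternatives). The number of called miRNAs was 4 without BPA 918, 5 without BPA 910, 15 without BPA 984 and 15 with 1 adjustment over the 4 tables. With 1 size factor over the 4 tables, chosen after seeing the data, 65 miRNAs were called and MIR26B and MIR381 were at 0.44 and 0.12.

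Of 28 tested miRNAs of the imprinted DLK1-DIO3 region, the locus of the callipyge muscle trait in sheep, 1 rose, 2 fell and 25 did not pass. MIR409 rose from 84.5 ± 26.7 to 218 ± 50 (limma adjusted p = 0.0093), while MIR154A fell from 16.1 ± 2.07 to 5.18 ± 2.29 (adjusted p = 0.0124) and MIR381 from 21.7 ± 4.8 to 8.93 ± 3.98 (adjusted p = 0.0417). MIR154A did not pass without BPA 918 (limma adjusted p = 0.0685; 0.0018 to 0.6470 over all alternatives), nor MIR381 without control 902, 924 or 928 or without BPA 910, 918 or 977 (0.0573 to 0.1361; 0.0115 to 0.8129 over all alternatives). Adjusted over the list alone, 5 of the 28 passed. Of 8 fibrosis-related miRNAs, MIR200B rose and 7 did not pass, and of 4 miR-17/92 family members MIR25 rose and 3 did not pass. Adjusted over each list alone these counts were also 1 and 1. None of 7 insulin and lipid metabolism miRNAs, 7 let-7 miRNAs or 4 fibroblast and smooth-muscle miRNAs passed, over all miRNAs or over the list alone. No list of the 6 shifted in 1 direction as a set (camera adjusted p of 0.9401 for each, and 0.9548 with an estimated correlation). A test of members changing in either direction (limma fry, mixed), read after the data were seen, gave an adjusted p of 0.0011 for fibrosis-related, 0.0038 for DLK1-DIO3 and 0.0144 for insulin and lipid miRNAs, and of 0.4467 to 0.8440 for the other 3 lists. The fibrosis-related list had a mean log2 fold change of 0.11 and a median of -0.11. Of the liver-enriched, leukocyte and endothelial lists, no member passed. MIR148A and MIR194, both enriched in liver, had log2 fold changes of -0.05 ± 0.20 and 0.05 ± 0.17, leukocyte MIR150 of 0.07 ± 0.36 and endothelial MIR221 of 0.36 ± 0.28 (SE, limma adjusted p of 0.9080, 0.9080, 0.9133 and 0.5019).

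**Figure D2:**
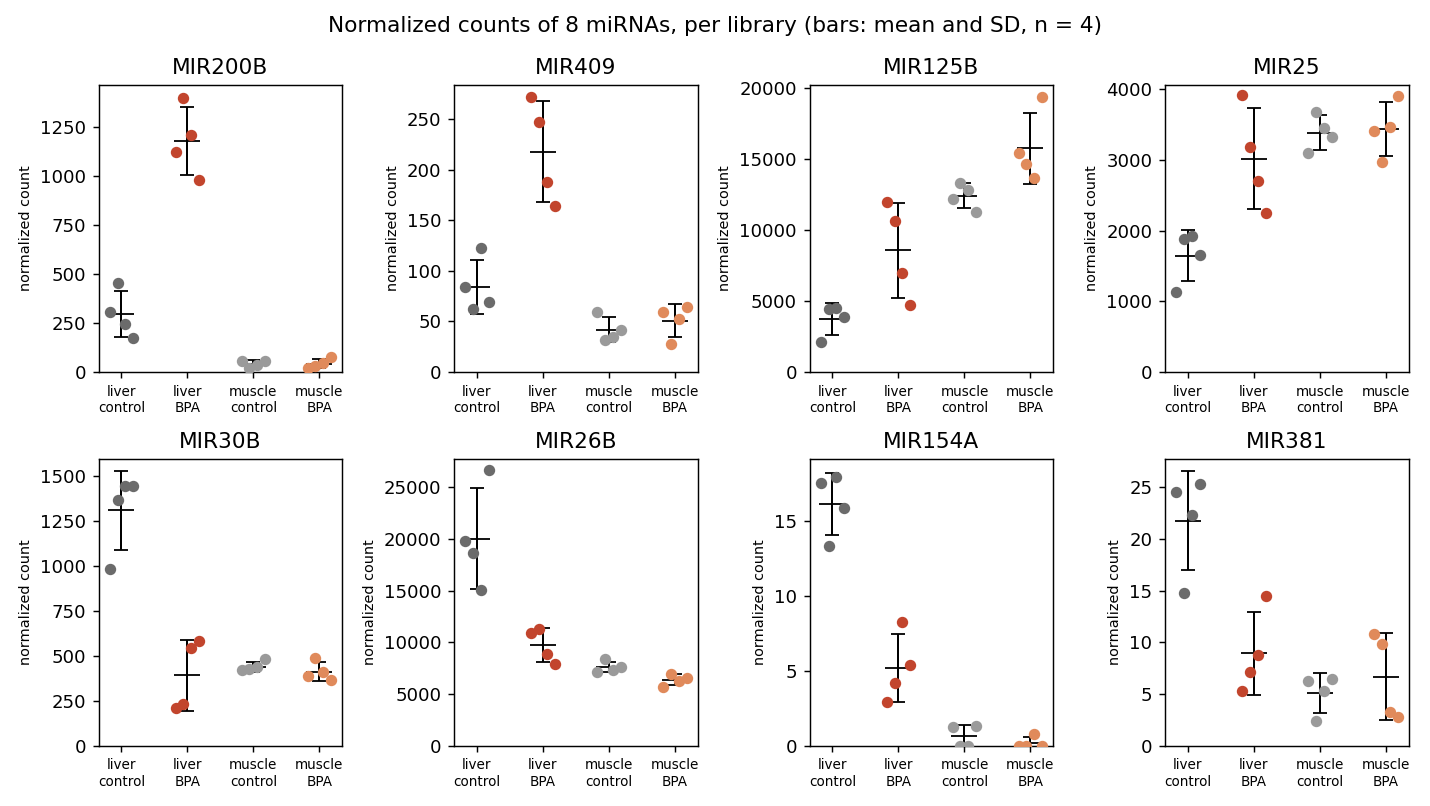
Normalized counts of 8 miRNAs called in liver in each of the 16 libraries, with mean and SD (n = 4). Scales are set within each tissue, so liver and muscle levels are not on a common scale; MIR200B lies between 980 and 1395 in BPA livers and between 174 and 453 in control livers.

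More transcripts of the other classes were called in liver. Within their own tables, 50 snoRNAs rose and 56 fell of 212 tested, 25 snRNAs rose and 20 fell of 53, and 20 lncRNAs rose and 24 fell of 124. With the miRNAs this made 204 of 467 transcripts, 100 higher and 104 lower (limma, BH within each table). The snRNAs LOC114113424 and LOC114108902 rose relative to other snRNAs, from 0.622 ± 0.238 to 49.3 ± 23 and from 0.68 ± 0.899 to 33 ± 9.27 (limma adjusted p = 4.44e-06 and 1.56e-05). Among snRNAs, 1 read was worth 0.19 to 0.33 in the control livers and 1.99 to 7.23 in the BPA livers. Both loci thus had few reads in every liver, and the size of their rise depends largely on the snRNA size factors. The lncRNA locus LOC105607806 fell from 2043 ± 921 to 30.7 ± 9.15, and LOC101110918 from 1060 ± 617 to 15.3 ± 8.43 (limma adjusted p = 6.09e-06 for both). In the reference gene table the first holds a tRNA and an snRNA gene and the second holds snoRNA genes, so their reads cannot be assigned to the lncRNA itself. Because the 4 tables were scaled separately, these directions hold only within a class. With the miRNA size factors used for every table, a scaling chosen after seeing the data, 11 transcripts were higher and 191 lower, 54 of the 204 calls changed sign, and LOC114113424 and LOC114108902 were at -0.17 and 0.27 (limma adjusted p = 0.8533 and 0.8122, from 2.58e-18 and from 1.01e-08 over all alternatives). Without control 928, 27 lncRNA loci were called. Within library codes up to 79 there were 1 control and 2 BPA livers, and the other ranges held livers of 1 treatment only, so the codes are largely confounded with treatment. With the code range as a covariate, 108 transcripts were higher and 74 lower, and MIR409, MIR154A and MIR381 had a limma adjusted p of 0.0973, 0.0625 and 0.1489 (MIR409 from 1.38e-05 to 0.0973 over all alternatives).

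In muscle of BPA animals, of 162 snoRNAs tested 43 rose and 10 fell, with log2 fold changes from -1.51 to 5.28. LOC114118129, an snoRNA of 80 nt, rose from 12.1 ± 2.11 to 373 ± 69.2, and LOC114110194, of 70 nt, rose from 9.29 ± 2.57 to 213 ± 7.7 (limma adjusted p = 2.27e-21 and 4.25e-19). LOC114117367, of 132 nt, fell from 140 ± 34.6 to 57.9 ± 18.7 (adjusted p = 1.49e-05). Among snoRNAs with a known length, 41 of 83 up to 90 nt rose and 1 fell, whereas 0 of 68 longer ones rose and 9 fell. The limit of 90 nt was not among the settings fixed in advance. It lies just above the longest snoRNA that rose (89 nt), so the 0 follows from its place. Scaled by the miRNA size factors, a setting chosen after seeing the data, 51 of the shorter ones rose and 0 fell, and 3 of the longer ones rose and 2 fell. A trend with length was also present in liver (Spearman rho of length and log2 fold change -0.41, against -0.68 in muscle), where 29 of 99 snoRNAs up to 90 nt rose and 14 fell, and 17 of 100 longer ones rose and 36 fell. Of 151 lncRNA loci, 6 rose and 2 fell, among them LOC114114830 from 35.7 ± 2.89 to 14.9 ± 2.81 (limma adjusted p = 0.0058; from 0.0012 to 0.5067 over the alternatives, the highest with no filter). Over the 4 tables, 61 of 417 transcripts were called, 49 higher and 12 lower. The number that fell was 20 without BPA 977, 7 without control 928, 6 without BPA 910 and 5 without BPA 984.

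**Figure D3:**
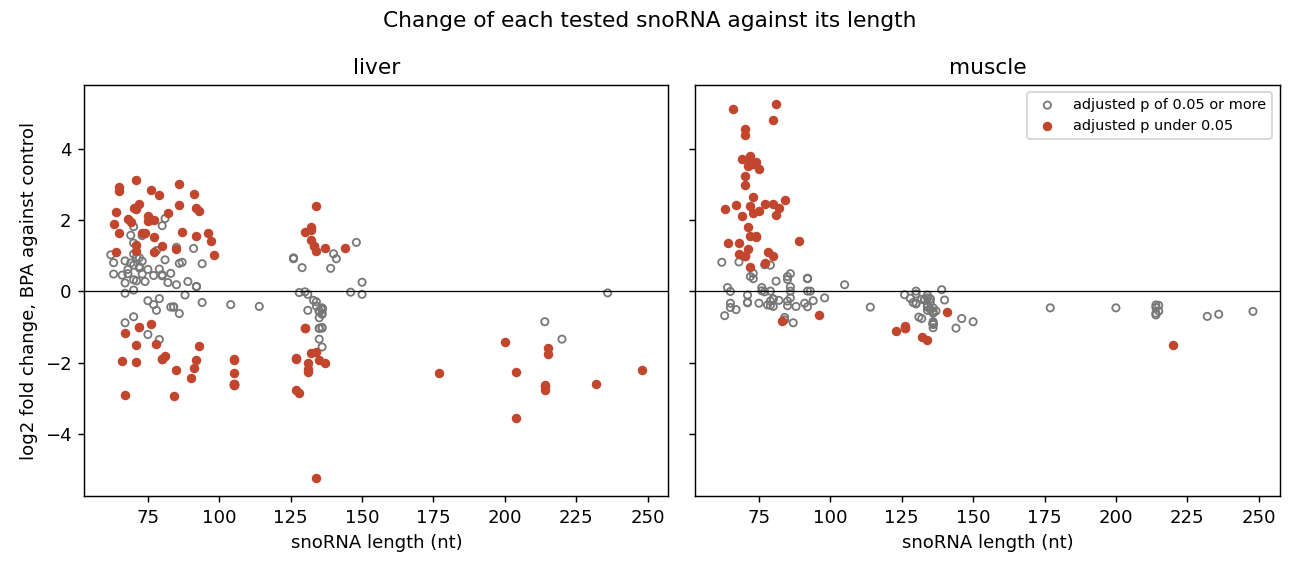
Log2 fold change (BPA against control) of each tested snoRNA against its length in nucleotides, in liver and in muscle; filled points have a limma adjusted p under 0.05. In muscle the snoRNAs that rose on the scale of their own table, by up to 5.28, are all 90 nt or shorter among those with a known length.

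No miRNA or snRNA passed in muscle. Among 70 miRNAs, 0 were called by limma, edgeR or DESeq2, with 3 at an unadjusted p under 0.05, and among 34 snRNAs 0 were called by limma, edgeR or DESeq2, with 0 at an unadjusted p under 0.05. Without BPA 977, limma called 8 snRNAs. The smallest p among higher miRNAs belonged to MIR125B, MIR495 and MIR127, with log2 fold changes of 0.34 ± 0.13, 0.74 ± 0.34 and 0.29 ± 0.14, and among lower ones to MIR26B, MIR29A and MIR143, at -0.26 ± 0.12, -0.26 ± 0.13 and -0.51 ± 0.27 (SE, limma adjusted p = 0.7060 for each). The 4 fibroblast and smooth-muscle miRNAs, which include MIR143, were lower as a set (median log2 fold change -0.31, camera adjusted p = 0.0255), as were the 7 insulin and lipid metabolism miRNAs (median -0.22, camera adjusted p = 0.0256). With an estimated correlation both had an adjusted p = 0.3998, no member of either passed alone, and MIR143 belongs to both lists. Without control 924, BPA 910 or BPA 984 only 1 list passed, and without control 928 none did. The sets of fibrosis-related, let-7, miR-17/92 and DLK1-DIO3 miRNAs did not pass (camera adjusted p = 0.3444, 0.9870, 0.6917 and 0.2676), and 0 of their members were called, over all miRNAs or over the list alone. Leukocyte MIR150 and endothelial MIR221 were at 0.13 ± 0.19 and 0.01 ± 0.19, and liver-enriched MIR148A and MIR194 at -0.06 ± 0.17 and -0.13 ± 0.23 (SE, limma adjusted p = 0.8461, 0.9760, 0.8696 and 0.8461). The library codes in the labels run from 73 to 76 in control muscle and start at 77 in BPA muscle, so code order and treatment cannot be told apart in this tissue. With quantile normalization the called transcripts became 40 higher and 52 lower. They became 63 and 3 with the miRNA size factors, 57 and 5 with 1 size factor over the 4 tables, and 43 and 28 with reads thinned to the shallowest library, all chosen after seeing the data.

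The BPA effect differed between the tissues for 168 of 462 transcripts, comprising 2 miRNAs, 90 snoRNAs, 34 snRNAs and 42 lncRNA loci (limma interaction, BH within each table). MIR200B rose in liver but had a log2 fold change of -0.02 ± 0.39 in muscle (interaction -2.08 ± 0.53, limma adjusted p = 0.0344), and MIR30B fell in liver with -0.10 ± 0.15 in muscle (interaction 1.77 ± 0.40, adjusted p = 0.0215). With the replicate block of animals 145 transcripts and 0 miRNAs passed, MIR30B at a limma adjusted p of 0.0925 and MIR200B at 0.1973 (4.60e-04 to 0.7566 and 7.42e-06 to 0.5396 over all alternatives). MIR200B did not pass without animal 902, 924, 928, 910, 918 or 977 (limma adjusted p from 0.0978 to 0.2747), nor MIR30B without 908, 924, 928, 910 or 918 (0.0584 to 0.1582). Without animal 984, 9 miRNAs passed, among them MIR381, MIR25 and MIR409 (0.0472, 0.0273 and 0.0474). Called lncRNA loci numbered 22 without animal 928 and 20 without 977. With all animals and adjustment within each table, MIR26B, MIR25, MIR381 and MIR409, called in liver, did not pass the interaction (limma adjusted p = 0.1083, 0.1083, 0.2331 and 0.2331). With 1 adjustment over the 4 tables, the number of miRNAs that passed was 5, among them MIR26B, MIR25 and MIR409 (limma adjusted p = 0.0178, 0.0209 and 0.0454; 0.0036 to 0.3502, 3.01e-05 to 0.4188 and 4.90e-05 to 0.4489 over all alternatives). With 1 size factor over the 4 tables, chosen after seeing the data, 70 miRNAs passed, and the interaction of MIR26B turned from 0.77 to -1.21. Of lncRNA loci, LOC101110918 was at 15.9 ± 1.66 and 16.8 ± 6.16 in control and BPA muscle, against its fall in liver (interaction 6.02 ± 0.61, limma adjusted p = 1.11e-06). LOC114118468, a locus that holds tRNA genes, was at 3025 ± 288 and 158 ± 68.3 in control and BPA liver and at 216 ± 34.8 and 259 ± 87 in muscle (interaction 4.57 ± 0.47, adjusted p = 1.11e-06). The snRNA loci LOC114117116 and LOC114117117, near-identical copies of 191 nt whose reads cannot be separated, had interactions of -5.56 and -5.58 (limma adjusted p = 2.02e-06). With the miRNA size factors these were 0.85 and 0.84, and 215 transcripts were then higher and 1 lower in the interaction. None of the 6 miRNA lists passed in the interaction (camera, smallest adjusted p = 0.5587, and 0.6608 with an estimated correlation; limma fry, mixed, 0.1198). Of their members MIR200B was called, and adjusted over the list alone 1 fibrosis-related miRNA and 1 of the miR-17/92 family passed.

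Across the 360 transcripts tested in both tissues, the BPA effects of liver and muscle were not correlated beyond chance (Pearson r = 0.09, exact permutation p = 0.6286; Spearman rho = 0.11, exact p = 0.6857). By class, r was 0.22 for 70 miRNAs, 0.27 for 158 snoRNAs, -0.85 for 33 snRNAs and -0.10 for 99 lncRNA loci, with exact p of 0.6857, 0.3714, 0.1143 and 0.7429 (0.7429, 0.7429, 0.4571 and 0.7429 after Benjamini-Hochberg adjustment over the 4 classes). Transcripts are not independent replicates, and the permutation is over animals.

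Between the tissues, MIR133, a miRNA of striated muscle, was at 321523 ± 50587 in muscle and 266 ± 238 in liver (SD, n = 8; limma adjusted p = 6.22e-16), and MIR194 and MIR148A were higher in liver, at 9357 ± 857 against 142 ± 35.3 and 40814 ± 9008 against 1507 ± 263 (adjusted p = 7.75e-18 and 4.14e-16). Each tissue was scaled alone, so each log2 fold change (muscle against liver) is followed by its value after median-of-ratios rescaling over both tissues. These were 10.61 and 11.19 for MIR133, -6.06 and -5.48 for MIR194, and -4.75 and -4.16 for MIR148A. Liver also held more MIR30A (-3.27 ± 0.12 and -2.69), and muscle more MIR362 (2.10 ± 0.17 and 2.67) and leukocyte MIR150 (2.52 ± 0.22 and 3.10; SE of the deposited value; limma adjusted p on the deposited scale 3.99e-15, 1.59e-09 and 4.03e-09). Of 26 DLK1-DIO3 miRNAs, 20 were lower in muscle, 0 were higher and 6 did not pass, whereas 17 were lower and 3 higher after rescaling. The set was lower by camera on both scales (adjusted p = 0.0289 as deposited, and 0.1958 with an estimated correlation, with which it passed on neither scale). Its members MIR494 (-3.55 and -3.00), MIR411A (-3.62 and -3.04), MIR3959 (-2.62 and -2.07) and MIR379 (-2.45 and -1.87) were lower on both. Of 7 let-7 miRNAs, 4 were higher and 1 lower in muscle on the deposited scale, and 7 were higher and 0 lower after rescaling (the set passed camera on both, with adjusted p = 0.0289 as deposited, and on neither with an estimated correlation, with adjusted p = 0.4331 as deposited). MIRLET7D was at 1.32 and 1.90, MIRLET7B at 1.21 and 1.79, MIRLET7C at 0.85 and 1.43, and MIRLET7A at 0.57 and 1.15. MIRLET7F, named after its values were seen, turned from -0.22 to 0.37 (limma adjusted p = 0.0383 as deposited).

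The counts of the remaining lists also depended on the scale. Of 8 fibrosis-related miRNAs, 7 were lower in muscle as deposited and 3 after rescaling, namely MIR200A (-5.91 and -5.36), MIR200B (-3.84 and -3.26) and MIR21 (-2.53 and -1.94). MIR29A (-0.74 and -0.15) and MIR199A (-0.83 and -0.24) no longer passed, nor did MIR29B-1 and MIR29B-2 (-0.49 and 0.08 for both), which were named after their values were seen. Of 7 insulin and lipid metabolism miRNAs, 1 was higher and 6 were lower as deposited, and 1 and 1 after rescaling. MIR30C (1.07 and 1.65) and MIR107 (-1.39 and -0.81) passed on both scales, while MIR103 (-0.72 and -0.14) did not pass after rescaling. Of 4 fibroblast and smooth-muscle miRNAs, 1 was higher and 3 were lower as deposited, and 1 and 1 after rescaling, with MIR10B at 4.45 and 5.03, MIR152 at -3.18 and -2.59, and MIR143 at -0.93 and -0.34. The miR-17/92 family had 2 higher, MIR106B (1.08 and 1.67) and MIR25 (0.64 and 1.22), and 2 lower, MIR106A (-2.18 and -1.72) and MIR17 (-1.12 and -0.55, but 0.54 with quantile normalization), on both scales. For this family the median as deposited (-0.24) and the direction of camera (up) differed in sign. These 4 sets did not pass on either scale (camera adjusted p for fibrosis, insulin, fibroblast and miR-17/92 miRNAs 0.1597, 0.8544, 0.9463 and 0.6428 as deposited). Endothelial MIR221 was at -0.64 ± 0.17 and -0.06 (limma adjusted p = 0.0022 and 0.7498, from 3.28e-04 to 0.8672 over its alternatives). Adjusted over each list alone, 20 DLK1-DIO3, 5 let-7, 7 fibrosis-related, 4 fibroblast, 7 insulin and lipid and 4 miR-17/92 miRNAs passed as deposited, and 20, 7, 3, 2, 2 and 4 after rescaling.

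The lncRNA loci LOC105604459 (10.18 and 9.78), inside the MIB1 gene in the reference table, and LOC114117239 (6.95 and 6.71) were higher in muscle. LOC114110111 (-6.08 and -6.48) and the snoRNA LOC114110520 (-3.07 and -2.48) were higher in liver (limma adjusted p as deposited, in this order, 1.80e-15, 2.44e-15, 8.02e-15 and 5.37e-09). In all, 284 of 462 transcripts differed, 96 higher and 188 lower in muscle. The split was 125 and 142 after median-of-ratios rescaling over both tissues, 120 and 136 with quantile normalization, 120 and 130 with edgeR and 124 and 144 with DESeq2. With the size factor settings chosen after seeing the data it was 124 and 138 (1 over the 4 tables) or 131 and 118 (that of the miRNAs).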

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

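The tests of library codes, animal state, snRNA handling, read depth, bile duct epithelium, the DLK1-DIO3 region and other splits were chosen only after the result was seen; the test of snoRNA length was set before. The 204 transcripts called in liver and the 61 in muscle were each matched by 1 of 35 splits, the real one, with at most 7 and 9 calls in the others. The 168 interaction calls were matched by 1 of 35 splits, with at most 2 in the others. The 284 tissue calls were matched by 1 of 100 drawn swaps of tissue within animals, with at most 223 in the others. These 4 counts were thus unlikely to arise by chance, though with 35 splits no share below 1 of 35 is possible. Splits that mix the groups also widen the spread within each side, which lowers their counts. None of this speaks of technical differences that follow the groups.

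The excess of snRNA reads in control livers stood apart. The range of library codes is argued against, because the means of different code ranges differed by at most 1.63-fold within a treatment group (single libraries by up to 3.31-fold in controls and 2.04-fold in BPA animals), against 152-fold between the group means. A state of the animals reaching both tissues is also argued against, since no control muscle library exceeded a BPA muscle library by more than 1.87-fold, while each control liver exceeded each BPA liver by at least 44.6-fold. Gain of snRNA fragments through handling or insert length in the control livers stays open: scaled to miRNA reads, 75.5% of the 53 tested snRNA loci were lower in BPA livers by over 1 log2 unit (median -4.75, from -9.76 to 0.27), neither nearly all nor few enough to exclude it. The share lay just above the limit set for arguing against such a gain. Copies with identical values counted as separate loci (the 45 snRNAs called in liver had 37 distinct profiles), so the share may depend on them. An effect of BPA limited to liver stays open as well and cannot be told apart from handling of these libraries.

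In BPA muscle 41 of 83 snoRNAs up to 90 nt rose and 1 fell, with a median log2 fold change of 0.81 over the 83. Length acting alike on all snoRNAs of the same length is argued against as the whole cause. After the trend with length was taken out of each library, 26 of 41 snoRNAs that rose still passed. Their median log2 fold change went from 2.35 to 1.34, however, and the calls among snoRNAs with a known length went from 41 higher and 10 lower to 26 and 27. Taking out an average trend leaves some snoRNAs above it and others below. A length effect that differs between snoRNAs therefore stays open. Depth is argued against too, as 36 of 43 still passed with 2825 snoRNA reads in every library, while the order of the library codes stays open. In liver, which took no part in choosing them, the 43 snoRNAs were higher by 1.37 log2 units in the 5 libraries with codes from 77 (4.53 to 6.66) than in the 3 with codes up to 76 (3.65 to 4.77), ranges that overlapped (exact permutation p = 0.0893), against 2.50 in muscle. The code difference was 2.06 among BPA livers (2 libraries against 2) and 1.32 among control livers, where only 1, 902, has a code up to 76. BPA minus control was 0.93 within the lower codes, which rests on that 1 control, and 1.67 within the upper codes. In liver the set thus went with both code order and BPA, and in muscle the 2 cannot be told apart. A first form of this test, on muscle codes alone, was decided by the design and was replaced.

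miRNAs made from shared transcripts moved apart in liver. MIR200A, a neighbour of MIR200B and like it a marker of bile duct epithelium, had a log2 change of -0.14. Its upper 95% bound of 0.56 lay below the lower bound of 1.43 for MIR200B. More bile duct cells alone would raise both, which was not seen. This difference was the pattern that prompted the test, so the test gives no independent evidence on bile duct cells. MIR200C was at 0.54 (-0.82 to 1.89), an interval too wide to decide. The 28 DLK1-DIO3 miRNAs scattered around their common change with a chi-square per degree of freedom of 4.35, against at most 2.75 in the other 34 splits of the livers. The members thus did not shift by 1 common amount. Members called in opposite directions had been seen before this test was chosen, and splits that mix the groups have larger standard errors. The members called lower, MIR154A and MIR381, had few reads in the control livers. A change of the region with further changes of single members cannot be told from these values. Depth is argued against, because 8 of the 9 called miRNAs still passed with 94393 miRNA reads in every liver library, the exception being MIR381 (limma adjusted p = 0.0746, from 0.0115 to 0.8129 over the alternatives). A processing step of single miRNAs, and a bias of the libraries towards particular sequences, were not tested.

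A test of the difference between tissues singled out 12 named transcripts besides the count of 168. The interactions, muscle effect minus liver effect in log2 units, were -2.08 for MIR200B and 1.77 for MIR30B. For lncRNA loci they were 6.02 for LOC101110918, 7.16 for LOC105607806 and 4.57 for LOC114118468. For snRNAs they were -4.75 for LOC114108902, -5.43 for LOC114113424, -5.56 for LOC114117116 and -5.58 for LOC114117117. For snoRNAs they were 4.37 for LOC114110194, 2.98 for LOC114118129 and -3.09 for LOC114117367. With the replicate block MIR200B and MIR30B did not pass (limma adjusted p = 0.1973 and 0.0925). The snRNA values depended on the scale. With the miRNA size factors, chosen after seeing the data, LOC114117116 and LOC114117117 had interactions of 0.85 and 0.84. The liver effects of LOC114113424 and LOC114108902 were then -0.17 and 0.27.

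Single libraries lay far from the other 3 of their group in 26 of 220 groups of values tested, where chance gives about 1 in 20. In control liver 902, MIR133 was at 717 (others 115 to 155), MIR10B at 584 (49.2 to 101), MIR103 at 528 (730 to 751), MIR30C at 1151 (1934 to 2063), MIRLET7A at 13069 (20331 to 21382), LOC114117116 at 34.3 and LOC114117117 at 35.6 (4.95 to 7.7). Control liver 908 had 10629 snoRNA reads (8000 to 8270) and control liver 928 had MIR148A at 50982 (36621 to 39075). BPA liver 910 had 1383538 miRNA, 3865 snRNA and 284321 lncRNA reads (at most 688052, 1308 and 115362 in the others) and MIR221 at 435 (694 to 703). MIR106A was at 20 in BPA liver 977 (11.9 to 12.9) and MIR133 at 574 in BPA liver 984 (122 to 164). In control muscle 902 there were 0.336 snRNA reads per 100 miRNA reads (0.246 to 0.252), LOC114114830 was at 40 (33.8 to 34.6) and MIR194 at 186 (129 to 139), and in control muscle 928 MIR494 was at 15.5 (10.1 to 10.6). In BPA muscle 984, MIR103 was at 302 (487 to 491), MIR143 at 5653 (13117 to 13862), MIRLET7A at 46393 (23820 to 25460), MIRLET7D at 5460 (2405 to 2750) and LOC114118468 at 388 (196 to 228). LOC114114830 was at 19.1 in BPA muscle 977 (13.4 to 13.6) and LOC114117367 at 85.8 in BPA muscle 918 (47.3 to 49.8).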

How the results depend on the processing

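The settings with 1 size factor for all tables, the miRNA size factors, thinned reads, single copies of identical loci, no nested lncRNA loci and the miRNA table alone were chosen after seeing the data. Counts of called transcripts stayed within 1.5 times under most settings. With a filter at a mean of 20, which leaves fewer transcripts, the liver count was 132 and the tissue count 165. Quantile normalization gave 92 in muscle, and thinned reads gave 102 in the interaction; the cause was not tested. The miRNA table alone gave 9 in liver, 0 in muscle, 63 between tissues and 2 in the interaction, by construction. Leaving out each replicate gave 156 to 195 in liver, 53 to 69 in muscle, 261 to 293 between tissues and 113 to 164 in the interaction. With the replicate block the tissue count was 276 and the interaction count 145, and among named transcripts and lists it changed no call except those of MIR30B and MIR200B.

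Of the fixed lists, the 2 called in muscle became 0 with an estimated correlation and 0 with fry, and 0 to 2 without single replicates (0 without control 928, and 1 without control 924, BPA 910 or BPA 984). The 2 called between tissues became 0 with an estimated correlation and 5 with fry, which asks only whether members move one way. The correlation of BPA effects was -0.01 with a filter at 20 and -0.03 to 0.21 without single animals (-0.03 without 902 or 910), never past its threshold; the cause was not tested.

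With 1 size factor over the 4 tables, MIR26B and MIR381 were at 0.44 and 0.12 in liver, and MIR30B, MIR26B and MIR381 at -0.20, -1.21 and -0.32 in the interaction. With the miRNA size factors LOC114113424 was at -0.17 in liver, and LOC114117116 and LOC114117117 at 0.85 and 0.84 in the interaction. Between tissues MIR17 was at 0.54 with quantile normalization, and MIR221, MIR29A and MIR103 at 0.11, 0.04 and 0.06 with edgeR. The size factor settings set these by their scale; for quantile normalization and edgeR the cause was not tested. MIR200B in liver passed under all 26 alternatives (limma, edgeR or DESeq2 adjusted p from 1.51e-09 to 0.0244), MIR381 failed under 13 of 25, MIR25 under 7 of 26 and MIR125B under 4 of 26. BPA livers held as few as 877 snRNA reads, and the limit this depth sets was not compared between classes.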

Other observations

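lncRNA reads were concentrated in few loci. In muscle, the top 2 loci took 89.8% to 93.7% of the lncRNA reads of each library, and LOC105604459 averaged 349762 ± 76601 normalized counts (SD, n = 8). In liver the top 2 loci took 40.8% to 46.5% in controls and 57.7% to 63.1% in BPA animals. Loci that hold an annotated small RNA took 31.6% to 35.5% of lncRNA reads in control livers, 16.3% to 18.9% in BPA livers and 1.45% to 2.36% in muscle. These shares are lower limits, because loci absent from the reference gene table took 51.5% to 55.7% of lncRNA reads in control livers, 67% to 68.6% in BPA livers and 34.4% to 54.8% in muscle. This unknown part differed between the liver groups, so the shares cannot be compared between them, and no test was made.

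MIR29A and MIR30A were lower in BPA liver without passing (log2 fold change -0.52 ± 0.18 and -0.59 ± 0.19 SE, limma adjusted p = 0.0790 and 0.0593). Both were chosen for this comparison after their values were seen. MIR29A was lower in 4 of 4 BPA livers than in any control liver, and also in 4 of 4 BPA muscles than in any control muscle. MIR26B likewise lay below all controls in 4 of 4 BPA libraries of both tissues, and MIR125B above them, with log2 fold changes of -0.26 ± 0.12 and 0.34 ± 0.13 in muscle (limma adjusted p = 0.7060 for both). These were the only such miRNAs of the 70 tested in both tissues, 1 higher and 2 lower. Chance puts 2.86% apart, on either side, in 1 tissue. The share that chance puts on the same side in both tissues is smaller if the tissues are independent, and was not computed.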
